A study of Mus musculus with 11 samples.

How the data were processed

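Gene expression was measured on Affymetrix arrays in total RNA from tumour-free liver of male C57BL/6 mice at 14 months of age. The labels put 3 arrays in the wild-type group, 4 in the Mdr2-KO group and 4 in the Mdr2-KO/IL6-KO group. Per the labels' protocols, RNA came from snap-frozen tissue and was converted to biotinylated cRNA. The authors deposited 1 table of log2 values, a level for each of 35557 probe sets on each of the 11 arrays, made by RMA in Partek per the submitters' processing notes. The versions and the background and summary settings were not given in the sources used here. The deposited log2 values were levels, not ratios, and were not centred per gene: array medians lay between 5.09 and 5.23. They were used without further normalization. The labels gave no batch, day, litter or pairing, so no such term could be fitted. Replicate numbers follow the order of the samples and pair nothing. Sample titles differed: wild-type titles carry numbers with the prefix W, and all knockout titles carry numbers with the prefix BIL. What these series stand for is not stated. Any difference between them cannot be told apart from genotype in the comparisons with wild type. No label states outright that each array came from its own mouse, and p-values measure the spread between these samples.

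Probe sets were named through the platform annotation supplied with the values, with symbols updated by Entrez identifier against a RefSeq gene table of assembly GRCm38.p6, which was used for names and neighbouring genes only. Of the 35557 probe sets, 21789 had 1 gene symbol, 1621 had several and 12147 had none there. Genes were tested on probe sets with 1 symbol, taking the probe set with the highest mean over all arrays where a gene had several, which was so for 998 genes. This left 19939 genes, of which 19856 matched the RefSeq table. No filter on dim genes was applied in the main test. Signal over background and its detection calls were not used here, so the number of arrays is the only stated limit on precision.

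The comparisons were made with limma 3.58.1 in R 4.3.3, in 1 linear model of the 11 arrays with a mean per group and 3 contrasts, moderated by eBayes, two-sided, with Benjamini-Hochberg adjustment over the 19939 genes. A gene was called at an adjusted p under 0.05. Errors of log2 fold changes are the SE from that model, and errors of group levels are the SD over arrays. The share of genes whose arrays do not overlap between groups would be 5.71% by chance for 3 against 4 arrays and 2.86% for 4 against 4. On simulated data with the spread of the 19939 real genes, the Mdr2-KO minus wild type contrast recovered 64% of genes changed 1.5-fold, 97.3% of those changed 2-fold and 100% of those changed 3-fold. The Mdr2-KO/IL6-KO minus Mdr2-KO contrast recovered 74% at 1.5-fold and 100% at 2-fold and 3-fold. Of 192 and 206 calls in these simulated contrasts 12 each were of unchanged genes. The simulation treats genes as independent of one another and gives each its moderated spread, equal in all groups. In it 50 genes were changed 1.5-fold, 75 were changed 2-fold and 75 were changed 3-fold. Collagen and matrix genes were also raised slightly in the simulated Mdr2-KO/IL6-KO arrays, and calls of them do not count as unchanged genes. With fewer true changes the adjusted threshold is stricter. The recovered shares therefore do not carry over to the real contrast between the knockout groups, where 1 gene was called.

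For groups of genes, 35 lists of pathways and cell-type markers were tested with camera (limma) at its preset inter-gene correlation of 0.01, two-sided, adjusted over the lists within a contrast. Of 837 list entries, 71 had no probe set of their own. The same lists were run with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. Counts of list members past the threshold are given over all genes and adjusted over the list alone.

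The genes named were set by a rule: Abcb4 and Il6; the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap, leaving out predicted loci; up to 3 members of a passing list and 1 of any other, by lowest p; where no gene passed in a direction, the 3 with the lowest p; and sex-linked genes as a check of the sex given in the labels. The groups, tests, lists, naming rule, windows around the targeted genes and the following alternatives were fixed before the data were examined. These were the mean of a gene's probe sets, only genes brighter than the median gene, quantile normalization, median centring, cyclic loess, eBayes with trend and robust, an unmoderated model, array weights, only the 2 groups compared, an added fold of at least 1.5, an adjusted p under 0.01, and leaving out each array in turn. Chosen after seeing the data were a fit with the array median as a covariate, a fit without Mdr2-KO replicates 2 and 3, and an exact permutation of list means over arrays.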

Results

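Liver RNA was profiled in 3 groups of male mice: wild type (n = 3 arrays), Mdr2-KO (n = 4) and Mdr2-KO/IL6-KO (n = 4). Mdr2, the product of Abcb4, is the canalicular transporter that moves phosphatidylcholine into bile, and mice without it develop bile duct injury, fibrosis and, later, liver tumours. Interleukin 6 is the main inducer of acute-phase proteins in hepatocytes. The samples were of tumour-free tissue at 14 months. Arrays were alike, with Pearson r over probe sets from 0.976 to 0.990 between any pair. The leading principal component held 28.2% of the variance and set the 3 wild-type arrays, at -23.3 to -20.1, apart from all 8 knockout arrays, at -5.84 to 15.7. The next component held 19.5% and was widest within the Mdr2-KO group, from -25.8 in replicate 2 to 21.0 in replicate 3.

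**Figure D1:**
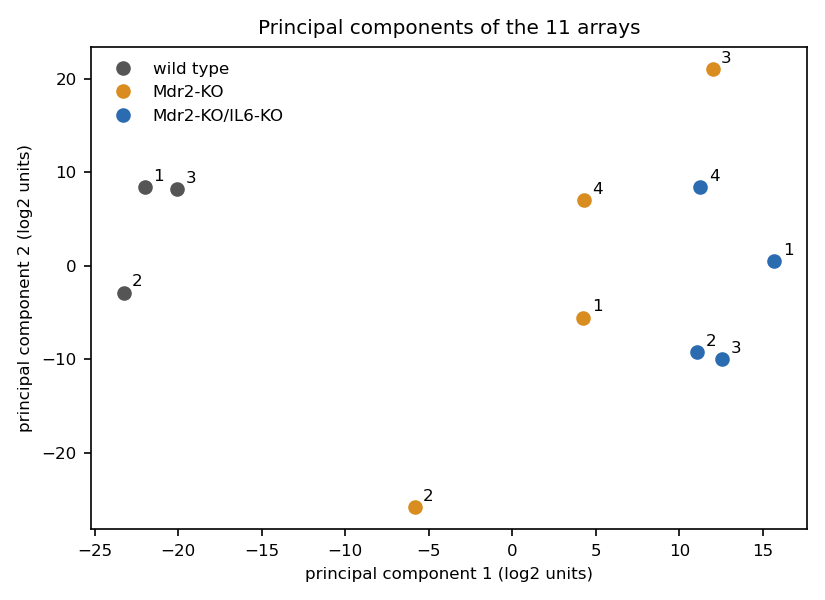
Scores of the 11 arrays on the leading pair of principal components of log2 levels, in log2 units; points are arrays, coloured by group and numbered by replicate. Wild-type arrays lie at -23.3 to -20.1 on the horizontal axis, and Mdr2-KO replicates 2 and 3 are at opposite ends of the vertical axis, at -25.8 and 21.0.

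The targeted genes were read as a check of the labels. The probe set 10519578 of Abcb4 had a log2 level of 9.83 ± 0.105 (SD, n = 3) in wild type, 7.74 ± 0.194 (SD, n = 4) in Mdr2-KO and 8.09 ± 0.204 (SD, n = 4) in Mdr2-KO/IL6-KO livers. It fell 4.26-fold in Mdr2-KO (log2 change -2.09 ± 0.13 SE, adjusted p = 2.22e-06) and 3.34-fold in Mdr2-KO/IL6-KO (log2 change -1.74 ± 0.13 SE, adjusted p = 6.75e-06), with no overlap of arrays. By array it read 9.80, 9.95 and 9.74 in wild type, 7.63, 7.81, 7.54 and 7.98 in Mdr2-KO, and 7.83, 8.14, 8.32 and 8.08 in Mdr2-KO/IL6-KO. Between the knockout groups Abcb4 did not pass the threshold (log2 change 0.35, adjusted p = 0.9995). The Il6 probe set read 1.80 ± 0.191 in wild type, 2.02 ± 0.0452 in Mdr2-KO and 1.91 ± 0.0916 in Mdr2-KO/IL6-KO (SD, n = 3, 4 and 4), with every array of the 11 between 1.62 and 2.09. This is near the bottom of the scale and so checks nothing about the Il6 label. Xist averaged 2.99, 3.09 and 2.89 and Eif2s3y, a Y-linked gene, 8.09, 7.96 and 8.03 in the same order, as in males; Mdr2-KO replicate 2 had the lowest Eif2s3y, 7.20.

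The comparison of Mdr2-KO with wild type asks what loss of the transporter does to non-tumour liver. Of 20 measured bile duct cell markers 13 rose, and 13 of 33 collagen and matrix genes rose (adjusted p = 0.0509 with an estimated correlation for the matrix list). Of 25 xenobiotic cytochromes 4 fell and 1 rose, and as a list they did not pass (camera adjusted p = 0.163), while the metallothioneins Mt1 and Mt2 fell. Cyp2c39, a member of the Cyp2c cytochrome family, rose 16.1-fold (log2 change 4.01 ± 0.16 SE, adjusted p = 2.48e-08), Cib3 rose 8.21-fold (adjusted p = 0.000125), and Abcb1b, a multidrug export pump related to Abcb4, rose 4.80-fold (adjusted p = 4.20e-05). Abcb1b lies within 10 Mb of Abcb4, and around Cyp2c39 10.1% of other genes within 5 Mb were called in a comparison with wild type, against 4.2% elsewhere. Tspan8 rose 4.29-fold, Abhd1 4.12-fold, the matrix proteoglycan Lum 3.45-fold, the neurotrophin receptor Ntrk2 3.41-fold and the integrin Itga8 3.35-fold. Abhd1 lies within 10 Mb of Il6, on the chromosome that also holds Abcb4. Mt2 fell 5.59-fold (log2 change -2.48 ± 0.49 SE, adjusted p = 0.0231) and Mt1 4.00-fold, both metallothioneins. Cyp2b9 fell 5.12-fold, Cyp2c37 5.12-fold, Cyp2c55 4.39-fold, the steroid hydroxylase Cyp17a1 4.59-fold and the fatty acid binding protein Fabp5 3.55-fold. In all, 252 of 19939 genes were called, 189 higher and 63 lower, and none of the 252 had overlapping arrays. Of all genes, 9.13% did not overlap, against 5.71% by chance.

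**Figure D2:**
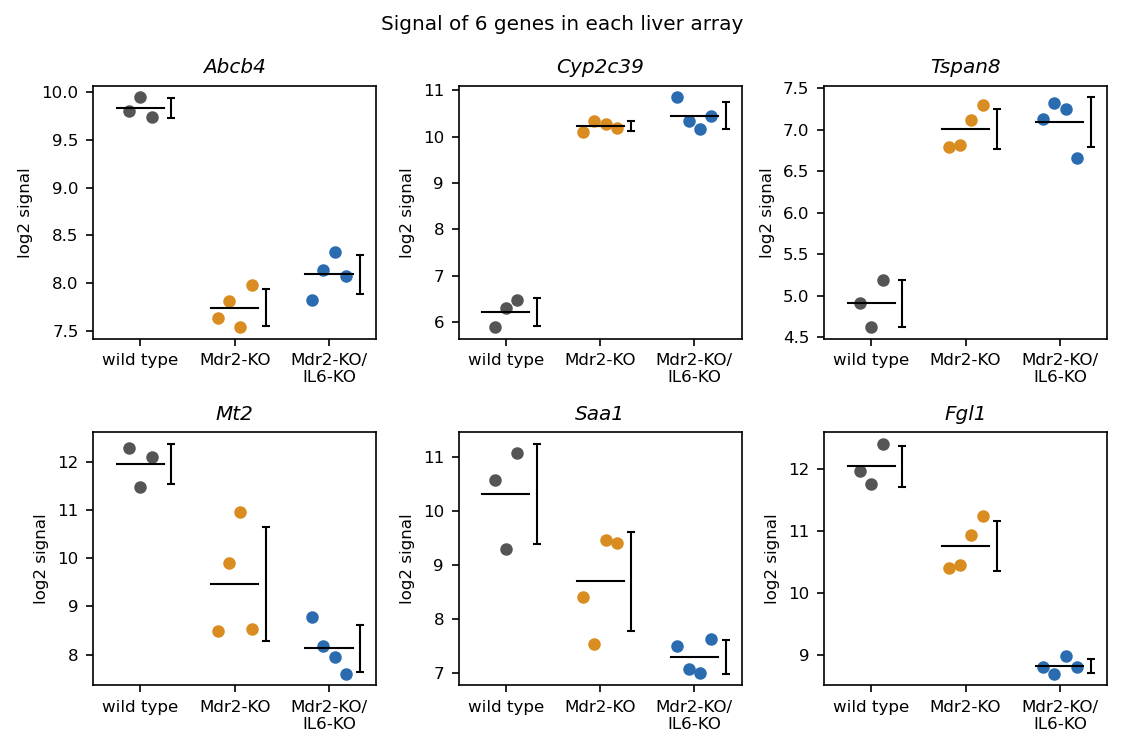
Log2 signal of 6 genes in each array, by group; points are arrays, horizontal lines are group means and bars beside them the SD (n = 3, 4 and 4). Abcb4 was 4.26-fold lower and Cyp2c39 16.1-fold higher in Mdr2-KO than in wild type, and Fgl1 was 3.84-fold lower in Mdr2-KO/IL6-KO than in Mdr2-KO.

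Among the gene lists in Mdr2-KO against wild type, bile duct and ductular cell markers stood out. Of 20 measured members 13 rose over all genes and 19 adjusted over the list alone, with none lower (camera adjusted p = 2.53e-32). This was the only list of the 35 to hold in this comparison with an estimated correlation (adjusted p = 0.00242). Cd24a rose 3.07-fold, the epithelial adhesion molecule Epcam 2.44-fold and Bicc1 1.96-fold. With fry, 4 of the 18 lists that passed camera held, all upward, and 14 did not. The 4 were bile duct cell markers (fry adjusted p = 7.82e-05), collagens and matrix (0.00219), fetal liver and liver cancer markers (0.00219) and stellate cells (0.0242). Collagen and matrix genes also rose, 13 of 33 over all genes and 18 adjusted over the list alone (camera adjusted p = 3.66e-26; adjusted p = 0.0509 with an estimated correlation), among them Dpt 3.05-fold, Col6a3 2.0-fold and Col3a1 1.82-fold. Of 24 stellate cell and myofibroblast genes 4 rose, and 10 rose and 1 fell adjusted over the list alone, with Tgfb3 up 1.92-fold, Pdgfd 1.78-fold and Pdgfra 1.67-fold (camera adjusted p = 8.63e-06; adjusted p = 0.181 with an estimated correlation). Of 16 markers of recruited monocytes and scar-associated macrophages 3 rose and 1 fell, and 5 and 1 adjusted over the list alone. Mmp12 rose 3.06-fold and Gpnmb 2.26-fold while Fabp5 fell (camera adjusted p = 0.00354; adjusted p = 0.385 with an estimated correlation). NRF2 and glutathione genes rose in 3 of 20 cases, 9 adjusted over the list alone, with Gsta4 up 2.12-fold, Gstp1 1.61-fold and Ephx1 1.58-fold (camera adjusted p = 4.51e-08; adjusted p = 0.216 with an estimated correlation). Of 21 fetal liver and liver cancer markers 3 rose and 1 fell, 4 and 2 adjusted over the list alone, with Tspan8, Golm1 (1.81-fold) and Robo1 (1.73-fold) higher (camera adjusted p = 0.0190; adjusted p = 0.181 with an estimated correlation).

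The other lists shifted upward in Mdr2-KO were endothelial cells (1 of 21 rose, Cd34 2.42-fold; camera adjusted p = 0.0114, and adjusted p = 0.338 with an estimated correlation), immediate early and heat shock genes (1 of 20, Klf6 1.61-fold; 0.0190 and 0.262) and the cell cycle (0 of 35; 0.00263 and 0.539), in each of which at most 2 members passed adjusted over the list alone. Acute-phase proteins shifted down, with 5 of 28 lower over all genes and 15 lower and 2 higher adjusted over the list alone (camera adjusted p = 5.26e-13; adjusted p = 0.216 with an estimated correlation). By array the list means overlapped between the groups (exact permutation p = 0.143): Mdr2-KO replicates 3 and 4, at -0.10 and -0.43, lay above wild-type replicate 2, at -0.44. Besides the metallothioneins, the secreted hepatocyte protein Fgl1 fell 2.44-fold, Serpina3n 1.79-fold and Itih4 1.41-fold. Metabolic lists that shifted down were fatty acid oxidation and PPAR-alpha targets (1 of 28 fell, Fgf21 1.98-fold; camera adjusted p = 5.87e-09, and adjusted p = 0.262 with an estimated correlation), cholesterol synthesis (1 of 20, Cyp51 1.60-fold; 3.55e-09 and 0.266) and lipogenesis (1 of 21, Acacb 1.92-fold; 0.000465 and 0.338). Adjusted over the list alone 4, 3 and 3 of their members fell. Immune lists shifted down with no member passing over all genes: interferon-stimulated genes (camera adjusted p = 3.16e-05, and adjusted p = 0.338 with an estimated correlation), T and NK cells (0.000192 and 0.338), B and plasma cells (0.00815 and 0.216) and neutrophils (0.0419 and 0.266). Adjusted over the list alone 3, 4, 0 and 0 of their members fell and 1, in T and NK cells, rose. The list of hepatocyte secreted proteins and transcription factors, hepatocyte secreted proteins for short, shifted down by a mean of 0.07 on the log2 scale. None of its members passed over all genes (camera adjusted p = 0.0419 for the list, and 0.262 with an estimated correlation).

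In this comparison 17 lists did not pass. They were IL-6 family and STAT3 signalling (camera adjusted p = 0.247), Kupffer cells and macrophages (0.497), antigen presentation (0.855), cytokines and chemokines (0.497, with Cxcl14 up 2.80-fold), p53 targets and senescence (0.0603, with Igfbp7 up 1.78-fold), lipid uptake (0.0812, with Plin2 down 1.61-fold), bile acid synthesis and transport (0.473), xenobiotic cytochromes (0.163, 1 higher and 4 lower), hepatocyte amino acid metabolism (0.247), complement (0.646), male-biased genes (0.163), female-biased genes (0.412, with 2 of 13 lower), the unfolded protein response (0.568), the circadian clock (0.556), erythroid cells (0.0522), pancreas, fat and muscle markers (0.109) and the respiratory chain (0.0642). Mean and camera direction differed in sign for antigen presentation and complement, and median and mean differed for the unfolded protein response and complement. Leaving out wild-type replicate 1, 2 or 3 took the count of 252 called genes to 149, 148 or 163, and without replicate 3 the higher calls were 90 and the lower 73. The unmoderated model called 43. The calls of Mt2, Mt1, Itih4, Pdgfra, Mmp12, Gpnmb, Gsta4, Gstp1, Golm1, Klf6, Fgf21, Cyp51 and Acacb each ended when some single array was left out; the highest adjusted p was 0.182, for Klf6 without wild-type replicate 2, and that of Mt2 was 0.116, without wild-type replicate 1. Some list shifts also ended without 1 array, given here with the array that raised the adjusted p most. Without wild-type replicate 1 these were neutrophils (0.281) and T and NK cells (0.237), and without wild-type replicate 2 lipogenesis (0.0665). Without wild-type replicate 3 they were endothelial cells (0.259), hepatocyte secreted proteins (0.204), immediate early genes (0.134) and fetal liver markers (0.0502). Without Mdr2-KO replicate 3 they were the cell cycle and recruited monocytes (0.0959 each), and without Mdr2-KO replicate 2 B and plasma cells (0.0743).

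The comparison of Mdr2-KO/IL6-KO with Mdr2-KO asks what loss of interleukin 6 adds in livers without Mdr2. A single gene was called. Fgl1, a fibrinogen-like protein secreted by hepatocytes (probe set 10578352), had a log2 level of 12.0 ± 0.332 (SD, n = 3) in wild type, 10.8 ± 0.397 (SD, n = 4) in Mdr2-KO and 8.82 ± 0.115 (SD, n = 4) in Mdr2-KO/IL6-KO livers. It fell 3.84-fold between the knockout groups (log2 change -1.94 ± 0.18 SE, adjusted p = 0.00107), with all 4 arrays of each group apart. No gene passed in the upward direction: the lowest p were those of Map3k13 (1.43-fold higher, adjusted p = 0.302), Col12a1 (1.30-fold, 0.311) and Cpeb2 (1.61-fold, 0.354). Of these, Cpeb2 lies within 20 Mb of Il6. At an unadjusted p under 0.05 there were 961 genes, 555 of them higher. Of all genes 2.51% did not overlap between the groups, against 2.86% by chance.

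Acute-phase proteins were the list with the lowest camera p between the knockout groups. Their mean was 0.52 lower on the log2 scale (a change of -0.52), and besides Fgl1 no member passed over all genes, whereas 16 of 28 fell adjusted over the list alone (camera adjusted p = 5.82e-23; adjusted p = 0.242 with an estimated correlation). Itih4 was 1.46-fold lower (adjusted p = 0.0706) and Itih3 1.39-fold lower (adjusted p = 0.618). All 4 Mdr2-KO/IL6-KO arrays had a lower list mean than all 4 Mdr2-KO arrays (exact permutation p = 0.0286, the smallest that 4 against 4 can give; 0.25 after adjustment over the 35 lists). The IL-6 family and STAT3 list also shifted down, with 0 of 25 lower over all genes and 3 adjusted over the list alone (camera adjusted p = 0.00978; adjusted p = 0.280 with an estimated correlation). Its members with the lowest p were Stat3 (1.46-fold lower, adjusted p = 0.628), Steap4 (1.46-fold, 0.657) and Pim1 (1.32-fold, 0.830).

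No member of any other list passed over all genes between the knockout groups. Lists shifted down were cholesterol synthesis (camera adjusted p = 1.64e-10, and adjusted p = 0.326 with an estimated correlation), complement (0.00017 and 0.399), T and NK cells (0.00105 and 0.470), hepatocyte secreted proteins (0.00105 and 0.242), xenobiotic cytochromes (0.00267 and 0.280), neutrophils (0.00277 and 0.242) and lipogenesis (0.0288 and 0.655). In the cytochrome list Cyp2c54 was 2.21-fold lower (adjusted p = 0.0724) and Cyp2c50 1.71-fold lower (adjusted p = 0.411), and 4 of 25 members fell adjusted over the list alone. In complement C4b was 1.31-fold lower (adjusted p = 0.441). Lists shifted up were the cell cycle (2.75e-09 and 0.387), NRF2 and glutathione genes (0.000259 and 0.399), endothelial cells (0.000277 and 0.280), collagens and matrix (0.000302 and 0.453), fatty acid oxidation and PPAR-alpha targets (0.00255 and 0.639) and p53 targets (0.0258 and 0.242). Examples were Mki67, a proliferation marker, 1.41-fold higher (adjusted p = 0.981), and Pdk4 1.68-fold higher (adjusted p = 0.657). Adjusted over the list alone 1 member each rose in the NRF2, collagen and fatty acid oxidation lists and 1 fell in complement. None of the 15 shifted lists held with an estimated correlation, and fry called none. The p53 and lipogenesis shifts were each lost when any of 5 arrays was left out, with adjusted p up to 0.117 and 0.277, while the IL-6 family and the T and NK cell shifts were lost without Mdr2-KO replicate 3 (adjusted p = 0.0884 and 0.0546). The NRF2 shift was lost without Mdr2-KO replicate 2 (0.0651), the neutrophil shift without Mdr2-KO replicate 4 (0.0685), and the fatty acid oxidation shift without Mdr2-KO replicate 3 or Mdr2-KO/IL6-KO replicate 4 (at most 0.0707).

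The 20 lists that did not pass between the knockout groups were bile duct cells (camera adjusted p = 0.0530), stellate cells (0.754), Kupffer cells (0.620), recruited monocytes (0.564), B and plasma cells (0.348), antigen presentation (0.738), cytokines and chemokines (0.564), interferon-stimulated genes (0.620), lipid uptake (0.150, with Hsd17b13 2.13-fold higher at an adjusted p = 0.618), bile acid genes (0.564), hepatocyte amino acid metabolism (0.722), male-biased genes (0.248), female-biased genes (0.550), fetal liver and cancer markers (0.292, with Ly6d 2.86-fold higher at an adjusted p = 0.657), the unfolded protein response (0.108), the circadian clock (0.431), immediate early genes (0.693), erythroid cells (0.564), pancreas, fat and muscle markers (0.731) and the respiratory chain (0.564). Median and mean differed in sign for Kupffer cells, B and plasma cells and interferon-stimulated genes. The count of 1 gene was 0 in the unmoderated model 2 without wild-type replicate 1, Mdr2-KO replicate 2, or Mdr2-KO/IL6-KO replicate 3 or 4, and 5 without Mdr2-KO replicate 3, of which 2 were higher. Fgl1 was called in 24 of the 25 settings.

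The comparison of Mdr2-KO/IL6-KO with wild type asks how livers without both genes differ from normal. Here 836 genes were called, 580 higher and 256 lower, of which 828 had no overlap of arrays, and 16.3% of all genes did not overlap against 5.71% by chance. Cyp2c39 rose 18.8-fold (log2 change 4.23 ± 0.16 SE, adjusted p = 1.22e-08), Cib3 9.97-fold, Abcb1b 7.20-fold, Ly6d 6.38-fold, Tspan8 4.54-fold, Itih5 4.32-fold, the macrophage elastase Mmp12 4.24-fold and Abhd1 4.19-fold. Mt2 fell 14.2-fold (log2 change -3.82 ± 0.49 SE, adjusted p = 0.000671), Fgl1 9.37-fold (log2 change -3.23 ± 0.19 SE, adjusted p = 1.68e-06), Mt1 8.51-fold and the serum amyloid genes Saa1 8.09-fold and Saa2 6.18-fold. Cyp2c37 fell 8.21-fold, Cyp2c54 6.80-fold and Cyp2b9 6.68-fold. The log2 level of Saa1 was 10.3 ± 0.921 (SD, n = 3) in wild type, 8.70 ± 0.916 (SD, n = 4) in Mdr2-KO and 7.30 ± 0.308 (SD, n = 4) in Mdr2-KO/IL6-KO.

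Among the lists, 17 of 28 acute-phase proteins fell and none rose, and 22 fell and 1 rose adjusted over the list alone (camera adjusted p = 1.62e-24; adjusted p = 0.0726 with an estimated correlation). Serpina3n fell 2.47-fold and Itih4 2.05-fold. Of 25 IL-6 family and STAT3 genes 4 fell, and 4 fell and 1 rose adjusted over the list alone, with Steap4 down 2.30-fold, Stat3 2.05-fold and Pim1 1.55-fold (camera adjusted p = 0.0223; adjusted p = 0.207 with an estimated correlation). Steap4, and Cyp51 among the cholesterol genes, lie within 10 Mb of Abcb4. Bile duct cell markers rose in 14 of 20 cases and in 20 adjusted over the list alone (camera adjusted p = 9.43e-27), again the only list to hold with an estimated correlation (adjusted p = 0.00472). Anxa5 rose 2.75-fold, Epcam 2.56-fold and Krt23 2.48-fold. With fry, 16 of the 24 lists that passed camera held and 8 did not. Acute-phase proteins (fry adjusted p = 0.00141) were among those that held. Of 33 collagen and matrix genes 18 rose, 22 adjusted over the list alone, including Dpt 3.38-fold, Col6a3 2.29-fold and Col12a1 1.80-fold (camera adjusted p = 3.44e-25; adjusted p = 0.0569 with an estimated correlation). NRF2 and glutathione genes rose in 9 of 20 cases, 13 adjusted over the list alone, with Gsta4 up 2.91-fold and Ephx1 1.84-fold (camera adjusted p = 6.39e-10; adjusted p = 0.0957 with an estimated correlation). Of 20 cholesterol synthesis genes 8 fell, 16 adjusted over the list alone, among them the sterol demethylase Cyp51 2.14-fold and Idi1 1.75-fold (camera adjusted p = 2.02e-16; adjusted p = 0.0994 with an estimated correlation).

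The remaining upward lists against wild type were the cell cycle (2 of 35 rose, Mki67 1.65-fold and Cenpf 1.29-fold, and 13 adjusted over the list alone; camera adjusted p = 3.90e-10, and adjusted p = 0.207 with an estimated correlation), endothelial cells (3 of 21, Cd34 2.67-fold; 1.20e-05 and 0.0957), stellate cells (7 of 24, Pdgfd 1.87-fold; 7.34e-05 and 0.0957), p53 targets (3 of 23, Igfbp7 1.97-fold; 0.00294 and 0.0726), recruited monocytes (4 of 16 rose and Fabp5 fell 4.76-fold; 0.00445 and 0.386), fetal liver and cancer markers (4 of 21 rose and 1 fell; 0.0105 and 0.0794), immediate early and heat shock genes (3 of 20, Hspb1 2.03-fold; 0.0223 and 0.207) and the respiratory chain (1 of 30, Sdhc 1.27-fold; 0.0333 and 0.475). The remaining downward lists were T and NK cells (4 of 25 fell, Ccl5 2.75-fold and Gzma 1.52-fold; 2.79e-07 and 0.189), lipogenesis (2 of 21, Acacb 2.08-fold; 1.89e-05 and 0.207), hepatocyte secreted proteins (2 of 25, Foxa3 1.55-fold and Fetub 1.51-fold; 0.000187 and 0.0726), interferon-stimulated genes (3 of 23, Irgm1 1.94-fold; 0.000193 and 0.371), neutrophils (0 of 15; 0.000193 and 0.0726), B and plasma cells (0 of 17; 0.00294 and 0.0957), fatty acid oxidation (2 of 28 fell and Pdk4 rose 2.24-fold; 0.00294 and 0.460), complement (2 of 18 fell, C4b 1.67-fold and Cfi 1.44-fold, and 2 rose, C7 1.88-fold among them; 0.0137 and 0.460), xenobiotic cytochromes (6 of 25 fell and 3 rose; 0.0159 and 0.224) and erythroid cells (0 of 9; 0.0259 and 0.264). Foxa3 is one of the transcription factors of the hepatocyte list and not a secreted protein. Adjusted over the list alone 11 T and NK cell genes fell and 2 rose, 8 interferon-stimulated genes fell, 11 stellate cell genes rose and 2 fell, and 5 complement genes fell and 2 rose. By the same adjustment 5 endothelial, 6 p53, 4 monocyte, 7 fetal liver, 3 immediate early and 1 respiratory chain genes rose, and 1 p53, 1 monocyte and 2 fetal liver genes fell. Likewise 4 lipogenesis, 2 hepatocyte secreted, 3 fatty acid oxidation and 8 cytochrome genes fell, and 1, 0, 1 and 5 rose.

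The lists that did not pass against wild type were Kupffer cells (camera adjusted p = 0.33), antigen presentation (0.686), cytokines and chemokines (0.320, with 2 higher, Cxcl14 2.0-fold), lipid uptake (0.674), bile acid genes (0.253, with 2 genes higher and 1 lower, the bile acid receptor Nr1h4, 1.36-fold), hepatocyte amino acid metabolism (0.206), male-biased genes (0.0609, with 2 higher and 2 lower, Egfr 2.07-fold), female-biased genes (0.253, with 2 higher and 2 lower, Cyp17a1 4.47-fold), the unfolded protein response (0.167, with 1 higher and 2 lower, Xbp1 1.73-fold), the circadian clock (0.908) and pancreas, fat and muscle markers (0.252). Median and mean differed in sign for antigen presentation and the circadian clock, and for the clock the mean and camera differed too. The count of 836 became 464, 533 and 521 without wild-type replicates 1, 2 and 3, and 535 and 551 without Mdr2-KO/IL6-KO replicates 1 and 3. The calls of 19 named list members ended when some single array was left out, given here with the array that raised the adjusted p most. Without wild-type replicate 1 they were Cd8a (0.204), Gzma (0.166), Lyve1 (0.156), Eda2r (0.129), Ccl5 (0.101), Irgm1 (0.0810) and Ddit4l (0.0547). Without wild-type replicate 2 they were Stab1 (0.156), Mki67 (0.149), Sdhc (0.136), Jun (0.0928), Klf6 (0.0787) and Pim1 (0.0757). Without wild-type replicate 3 they were Iigp1 (0.176), Fetub (0.109), Mx2 (0.103), Fabp1 (0.0965), C7 (0.0908) and Cenpf (0.0817). Among lists, the IL-6 family shift ended without wild-type replicate 1 (0.137). Without wild-type replicate 3 those of complement, erythroid cells, fatty acid oxidation and cytochromes (0.0768 each) and of immediate early genes (0.106) ended, and without Mdr2-KO/IL6-KO replicate 4 that of the respiratory chain (0.318).

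**Figure D3:**
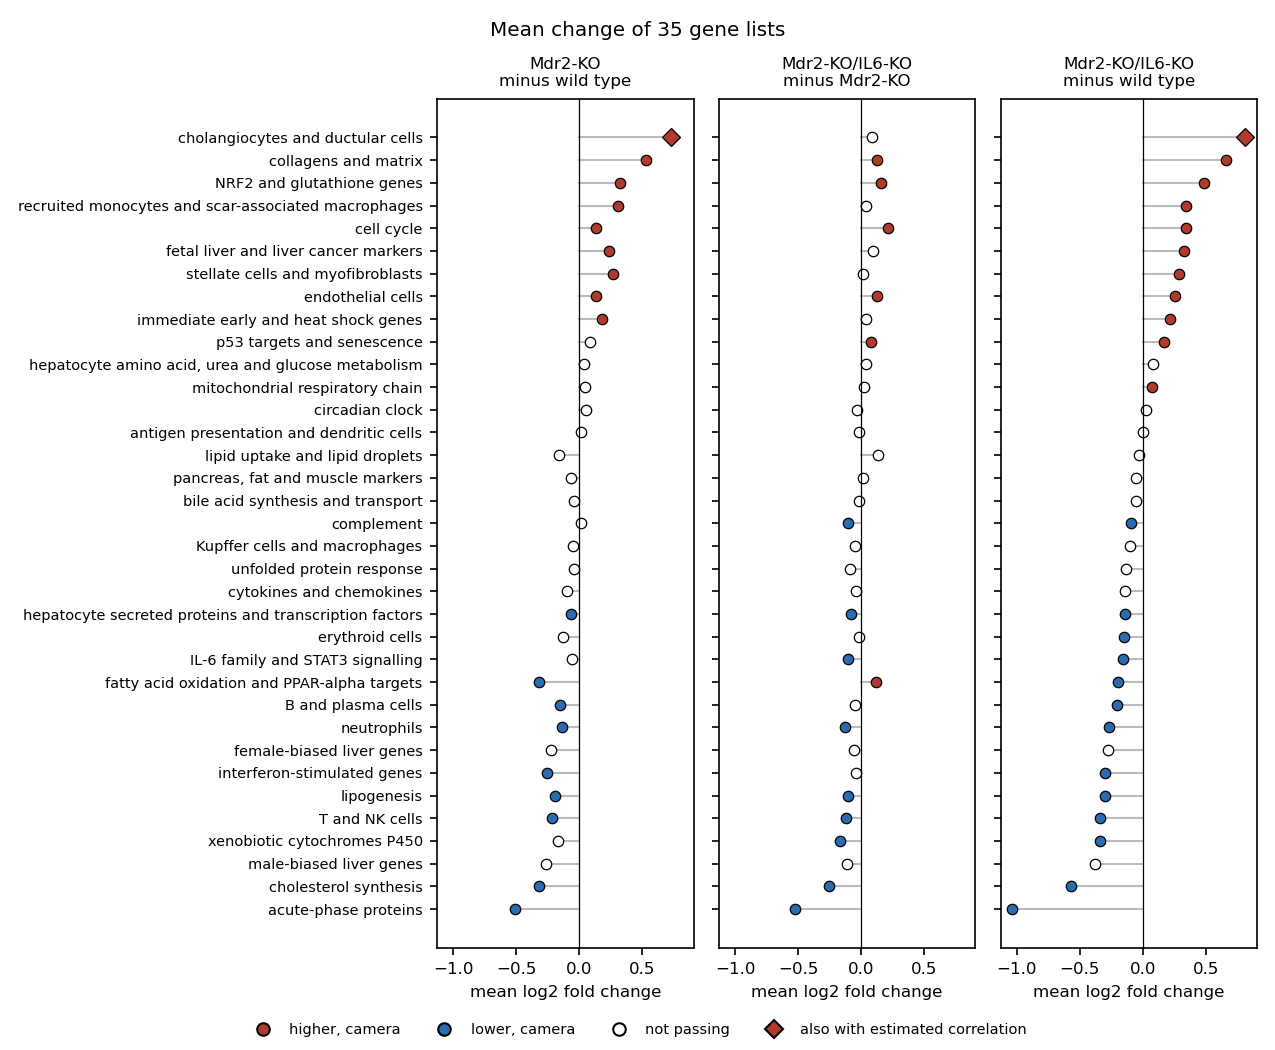
Mean log2 fold change of the members of each of 35 gene lists in the 3 comparisons (horizontal axis); red and blue symbols passed camera upward and downward, white circles did not, and diamonds also passed with an estimated correlation. Acute-phase proteins lie lowest in each panel, at -0.51, -0.52 and -1.04, and bile duct cell markers highest against wild type, at 0.73 and 0.82.

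Most genes called in Mdr2-KO were also called in Mdr2-KO/IL6-KO, which had more calls, 836 against 252. Of 189 genes higher in Mdr2-KO 182 were also higher in Mdr2-KO/IL6-KO, and of 63 lower genes 59 were shared; no gene was called in opposite directions. Independent lists would share 5.5 and 0.809 genes, but these lists are not independent, since both comparisons use the same 3 wild-type arrays. In 100 simulated draws of unchanged groups that share those arrays, at most 1 gene was called in the same direction in both. Those draws hold no true changes, so few calls could be shared in them. They cannot show how many of the real calls are shared through noise in the wild-type arrays. Over the 19939 genes, which are not independent, the log2 fold changes had a Pearson r of 0.852. The same simulated draws gave a mean r of 0.556, ranging from -0.416 to 0.972. The covariance was 0.0438 against a simulated mean of 0.0119 and a simulated maximum of 0.0472. The correlation and covariance thus lay within the simulated range, and the wild-type arrays are too few to split. A gene called against wild type in the double knockout alone is not shown to differ from Mdr2-KO. By the direct test Fgl1 alone passed over the 19939 genes with all arrays. Over the 25 settings, Gbp11, named after its values were seen, was called in 8 (adjusted p = 0.0582 with all arrays and genes), Itih4 in 4, and 7 other genes in at most 3 each.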

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

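The tests of hepatocyte content, of the distance between arrays after quantile normalization and of pancreas, fat and muscle markers were chosen or given their bounds after the results were seen, and the fit with the array median was added after seeing the data. Single arrays stood far from the other 3 of their group in 19 of 334 sets of 4 values tested, where chance flags about 5%. In the Mdr2-KO group, replicate 2 was low for Cd72 (5.73), Gstp1 (12.1), Iigp1 (8.64), Mmp12 (6.60) and Plg (11.9) and high for Fgf21 (6.03). Replicate 4 was low for Cpt1a (9.89) and Thrsp (8.85), replicate 1 for Il7r (4.43) and Pdk4 (5.42), and replicate 3 was high for Pdgfd (5.91). In the Mdr2-KO/IL6-KO group, replicate 4 was low for C7 (6.08) and Steap4 (10.1) and high for Cyp2c50 (8.90), replicate 3 was low for Ehhadh (9.75) and Elane (4.2), replicate 2 for Map3k13 (7.16), and replicate 1 was low for Tm7sf2 (8.82) and high for the mean of female-biased genes (4.80), all as log2 levels. Among probe sets outside the gene tests, those without a gene name had 3 calls higher and 6 lower than wild type in Mdr2-KO, and 22 higher and 17 lower in Mdr2-KO/IL6-KO, with 1 lower between the knockout groups. Those with several names had 9 higher and 4 lower in Mdr2-KO/IL6-KO.

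The mean of the acute-phase list was lower in all 4 Mdr2-KO/IL6-KO arrays than in all 4 Mdr2-KO arrays. Only 1 of its 28 members passed over all genes. The list passed camera at its preset correlation, but not with an estimated correlation (adjusted p = 0.242) and not with fry. By exact permutation of list means the p adjusted over the lists was 0.25, where a pass would need most lists at the smallest possible p. Array medians overlapped between the knockout groups, at 5.09 to 5.23 in Mdr2-KO and 5.13 to 5.20 in Mdr2-KO/IL6-KO. With the array median as a covariate the mean difference was -0.478 ± 0.153 (SE), against -0.522 ± 0.194 without it. Since the medians hardly differed by group, that fit could change the difference little and is a weak test of overall array intensity. A lower hepatocyte share would lower other hepatocyte genes alike. The list of hepatocyte secreted proteins and transcription factors shifted by -0.0759 ± 0.021 (SE). The gap between the acute-phase list and this one was -0.446 ± 0.191 (SE). Loss of interleukin 6 may account for the fall, but this stays open and untested: the allele and the breeding line cannot be separated in this design.

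Mdr2-KO replicates 2 and 3 lay at opposite ends of the second principal component. Over the 11 arrays that component followed the array median, with Pearson r = -0.936 (permutation p = 9e-05), Spearman rho = -0.855 (permutation p = 0.001) and r = -0.82 without the 2 arrays farthest from the middle. After quantile normalization both arrays were 44.5 score units apart, from 46.9 before, and the component held 17.5% of the variance, from 19.5%. This argues only against an even level difference left in the deposited values as the whole cause. Those values had already been processed by RMA, and array medians differed little. A further normalization could thus change little and is a weak test of technical causes. The 5 brightest pancreas, fat and muscle markers were higher in replicate 2 by a median of 0.429, with single differences from 0.164 to 0.739. Their log2 levels, 4.98 to 5.89, lay near the medians of replicates 2 and 3, 5.23 and 5.09. Differences at that level cannot show whether tissue other than liver was present, so it is not excluded. RNA quality that shifts genes unevenly and true differences between mice were not tested.

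For each count against wild type, only the real split among 35 called as many genes. These were 252 against at most 98 in another split for Mdr2-KO, and 836 against at most 53 for Mdr2-KO/IL6-KO. A share of 1 of 35 is the smallest that these splits can give, and both counts use the same wild-type arrays. Chance is thus less likely for these counts but is not excluded. Between the knockout groups, 4 of 35 splits, the real one included, called at least 1 gene, and another split called 2, so chance cannot be excluded for that count.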

How the results depend on the processing

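The fit with the array median, the fit without Mdr2-KO replicates 2 and 3 and the exact permutation of list means were chosen after seeing the data. No called gene or list named here changed direction in any setting. Of 4382 values of named genes under alternatives, 4110 kept their side of the threshold, 224 lost it and 48 gained it. Of 1368 values of called lists, 233 lost it. Those 233 include every value by exact permutation, where a pass was nearly out of reach. These were 18 for Mdr2-KO and 24 for Mdr2-KO/IL6-KO against wild type, and 15 between the knockout groups. For Mdr2-KO minus wild type, 252 calls became 43 in the unmoderated model, 410 with array weights, 138 with only the 2 groups compared and 94 at an adjusted p under 0.01, and between 148 and 323 without 1 array. For Mdr2-KO/IL6-KO minus wild type, 836 became 496 in the unmoderated model, 1341 with array weights, 445 with a fold of at least 1.5 and 342 at an adjusted p under 0.01, and between 464 and 989 without 1 array. For Mdr2-KO/IL6-KO minus Mdr2-KO, the count of 1 became 4 among genes brighter than the median gene and with cyclic loess, 2 with median centring, with eBayes trend and robust, with the array median as covariate and without both Mdr2-KO arrays, 6 with array weights, 0 unmoderated, and 1 to 5 without 1 array. The stricter thresholds lower counts by construction; for the others, leaving out arrays included, which raised some counts and lowered others, the cause was not tested. Gene lists called went from 18 to 1 with an estimated correlation, 4 with fry and 0 by exact permutation for Mdr2-KO minus wild type, from 15 to 0 in all 3 between the knockout groups, and from 24 to 1 with an estimated correlation, 16 with fry, all of them among the 24, and 0 by exact permutation for Mdr2-KO/IL6-KO minus wild type. The smallest p that the permutation can give is 0.0286, and after adjustment over 35 lists its lowest value was 0.0588. A list could pass only if most of the 35 lists reached that smallest p together. The permutation counts of 0 therefore say little about any single list. Without 1 array the lists called ranged from 14 to 21, 14 to 17 and 20 to 26. The share of higher calls moved by under 3 percentage points under the other scalings. Signal over background was not used here, so what it limits was not measured.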

Other observations

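The windows around the targeted genes were set beforehand; the other tests of this part, and the threshold of 0.001, were chosen after the results were seen. Genes of the Cyp2c family that neighbour each other moved in opposite directions in both knockout groups. Against wild type, Cyp2c39 was higher by 4.01 in Mdr2-KO and 4.23 in Mdr2-KO/IL6-KO on the log2 scale, whereas Cyp2c37 (-2.36 and -3.04), Cyp2c54 (-1.62 and -2.77), Cyp2c50 (-1.39 and -2.16), Cyp2c68 (-1.34 and -1.43) and Cyp2c55 (-2.13 and -1.94) were lower. Cyp2c29 was lower in Mdr2-KO/IL6-KO (-1.77, adjusted p = 0.000586) and did not pass in Mdr2-KO (-0.94, adjusted p = 0.065). Of the 13 Cyp2c genes measured there, 6 passed in neither comparison: Cyp2c70 (0.14 and 0.05), Cyp2c38 (-0.50 and -0.24), Cyp2c65 (-0.17 and -0.34), Cyp2c66 (-0.63 and -0.37), Cyp2c67 (-0.25 and -0.11) and Cyp2c23 (0.40 and 0.40). Cyp2c39 alone among the 13 rose. Cyp2c68 and these 6 were named after their values were seen.

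DNA of another strain around these genes is a candidate explanation for the opposite changes. Of 99 other genes within 5 Mb of Cyp2c39, 10 were called in a comparison with wild type (10.1%, against 4.2% elsewhere; Fisher exact p = 0.00914), and 2.94% of 16378 genes with at least 50 neighbours had as high a share around them. Nearby genes can also be regulated together, and no genotype was used here, so this remains a hypothesis.

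Targeted alleles can carry flanking DNA of the strain they were made in, and Abcb4 and Il6 lie on the same chromosome. Within 20 Mb of Abcb4, 8.85% of 113 genes were called in Mdr2-KO/IL6-KO against wild type, compared with 4.18% elsewhere (Fisher exact p = 0.0284, adjusted over 6 tests 0.17), and within 10 Mb 17.8% of 45 (Fisher exact p = 0.000511, not adjusted). Within 40 Mb it was 7.42% against 4.16% (Fisher exact p = 0.0107, not adjusted). Around Il6 in the same comparison, the share was 5.24% within 10 Mb (p = 0.39), 6.43% within 20 Mb (p = 0.0807) and 6.69% within 40 Mb (p = 0.0288), by Fisher exact tests without adjustment; the 20 and 40 Mb windows of both genes overlap and share called genes, so these shares are not separate results. The 8 called within 10 Mb of Abcb4 include Abcb1a and Abcb1b, which are related to Abcb4, and Cyp51 and Steap4, members of the cholesterol and IL-6 family lists. Abcb1a was named after its values were seen. In Mdr2-KO against wild type 3 of the 113 genes were called (2.65% against 1.26%, adjusted over 6 tests 0.344), all 3 within 10 Mb (6.67% of 45 against 1.25%, Fisher exact p = 0.0192, not adjusted). Near Il6, 2 of 249 genes had an unadjusted p under 0.001 between the knockout groups (Fisher exact p adjusted over 6 tests 0.265). Over the whole chromosome there were 6 such genes of 1138, compared with 21 elsewhere (0.527% against 0.112%, Fisher exact p = 0.00366). Among them, named after their values were seen, were Gbp11 (4.91-fold lower in Mdr2-KO/IL6-KO, adjusted p = 0.0582) and Fam126a (1.48-fold lower, adjusted p = 0.0706). Cpeb2 and Hsd17b13, given above, were also among them. Differences of strain DNA between the lines may contribute to the last result. Around each targeted gene, flanking DNA and effects of the knockouts cannot be told apart with these numbers of genes.

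Changes from wild type tended to be larger in Mdr2-KO/IL6-KO than in Mdr2-KO livers. Of 650 genes called for all 8 knockout arrays against wild type, 81.2% had the larger change in Mdr2-KO/IL6-KO. Over the 70 assignments of the 8 arrays to 2 groups of 4, the exact p was 0.0571, and another assignment reached 82.8%, so chance was not excluded.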
